A study of Mus musculus with 6 samples.

How the data were processed

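The series holds 6 samples of mouse tumour tissue in 2 groups of 3, taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was purified with oligo(dT), and libraries were sequenced on a NovaSeq instrument. The submitters' processing notes name the genome build GRCm38, R 4.1.0 and DESeq2 1.26.0 without saying what each was used for. The aligner, the counting tool and the gene annotation are not given in the sources used here.

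The authors deposited 1 table for the whole series, with a gene name per row. Its 6 columns of per-sample values were not used, because their names match the labels of neither a single sample nor a single group. No normalization, filter, model or test was applied, and no sample depth is given. The tests and alternatives planned before the data were examined were not run, and the gene lists fixed at the same time were used only to count which of their genes the table lists.

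What is reported comes from the header of the table and from its gene names, read with Python 3.11.15. The gene names were matched exactly, with upper and lower case distinguished, to the symbols of GENCODE M21, an annotation of GRCm38. Of the 29445 names, 23804 (80.8%) are symbols of that annotation, and all 29445 are symbols in RefSeq's annotation of GRCm38.p6, as a second matching chosen later showed. Genes of the fixed lists were matched to the table by exact name, without older or newer synonyms, so that a gene listed under a synonym counts as not listed. None of these matchings was planned before the data were examined.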

Results

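Poly(A)-selected RNA of mouse tumours was sequenced to compare treated with control tumours. The tumours grew from 4T1 cells, a mouse mammary carcinoma line, that had been injected into a mammary gland of BALB/c mice. The labels give 2 groups of 3 samples each. The control group is labelled 5% glucose, and the other group, called treated here, is labelled CM-ZIF8 at Ce6/Lon+L. ZIF8 is the usual name of a porous framework built from zinc and an imidazole, and Ce6 is the usual abbreviation of chlorin e6, a photosensitizer that forms reactive oxygen species under light. The labels do not expand CM, Lon or L, nor say whether L is part of the preparation or a separate step. The title of the series gives its purpose as altering tumour metabolism and strengthening the immune response to photodynamic therapy.

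The design implies a single comparison, of gene expression in treated against control tumours. That comparison was not made here. The table of the series has 6 columns of values, and their names consist of a first number, 1 or 7, and a second number from 1 to 3. Each first number heads 3 columns. The second number has the form of the replicate numbers in the labels, but neither the labels nor the table says which group is 1 and which is 7. An assignment by column order or by the values would have been a guess, and a wrong one would reverse the direction of every difference. A comparison of both sets of columns without a direction would need only that the first number marks the group, which the labels do not state either. It was left out by choice, because values were to be used only from columns whose names match the labels, and no expression value, fold change or p-value is reported for any gene.

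The table lists 29445 gene names, each once. Of 38 gene lists fixed before the data were examined, 19 describe pathways and 19 describe cell types. Together they name 567 different genes, of which 537 are among the gene names of the table. All 22 genes chosen for glycolysis and lactate handling are listed, among them Hk2, which encodes a hexokinase, and Ldha, which encodes a lactate dehydrogenase subunit. All 24 genes chosen for the interferon gamma response and antigen presentation and all 15 markers of cytotoxic T and NK cells are listed as well. By exact name, 9 of the 38 lists are incomplete. Of 15 T cell markers 12 are listed, without the receptor constant regions Trac, Trbc1 and Trbc2, and of 13 B and plasma cell markers 11 are listed, without Ighm and Igkc. Of 13 mammary gland genes 9 are listed, without the milk protein genes Csn1s1, Csn1s2a, Csn2 and Wap. Of 6 lymph node stroma genes 3 are listed, without Ccl21a, Ccl19 and Fdcsp. The hypoxia list has 19 of 20 genes by exact name, without Ero1l, which the table lists under its RefSeq name Ero1a. The incompleteness of that list is thus one of naming alone. The zinc response list has 4 of 5 genes, without Slc30a10. The erythroid list has 7 of 9 genes, without Hbb-b1 and Ahsp, and the mast cell list has 8 of 9, without Mcpt2. Of the 13 mitochondrially encoded respiratory chain genes, 0 are listed under the names used in the fixed list. With RefSeq synonyms allowed, a matching chosen later, 1 of them was listed. It was mt-Atp6 as Gm10925, which need not be the mitochondrial gene. Whether the others lack a row or only have no synonym in RefSeq that leads to their row was not checked. The 0 may thus come from naming or from rows left out, and does not show that these genes have no row. Being listed says that a gene has a row in the table. How the rows were chosen is not given, and a filter on detection was not checked for. Neither a listed nor a missing gene was therefore read as a level in any tumour.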

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

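No paired analysis was possible under the choice to use only columns matched by the labels, because no column of values was so matched. Without that choice, a fit of both sets of columns with the second number as a block could have been made, and it was declined. The labels do not say that a replicate number ties samples across the groups. For that reason the planned comparison had no replicate block, whether or not the columns could be matched. The other normalizations, filters and tools and the fits without 1 replicate were left out by the same choice, although those between both sets of columns need no direction, so how a difference between the groups depends on the processing is not known here. Both matchings that follow were chosen after the table had been seen. With RefSeq synonyms of GRCm38.p6 allowed, 539 in place of 537 genes of the fixed lists were listed, by Ero1l under the name Ero1a and by mt-Atp6, which RefSeq gives as a synonym of Gm10925, so that this match need not be the mitochondrial gene. All 29445 gene names of the table were symbols of RefSeq's annotation of GRCm38.p6, against 23804 that were symbols of GENCODE M21.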
